A study of Mus musculus with 15 samples.

How the data were processed

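RNA was measured on Affymetrix Mouse Genome 430 2.0 arrays in GFP-labelled neurons of the G42 mouse line, a line in which parvalbumin-class interneurons are marked. Per the labels, coronal slices of 400 µm were treated with protease at 1 mg/ml, the primary somatosensory cortex was dissected and dissociated, and fluorescent neurons were picked by hand under a microscope. Each array came from 1 animal, with 3 animals at each of 5 ages: postnatal day (P) 7, 10, 15, 25 and 40, the oldest group covering up to day 45. Between 23 and 85 cells were picked per animal. The RNA, between 0.3 and 1 ng a sample, went through 2 rounds of T7 amplification before hybridization. Sequencing depth has no counterpart here, so the number of arrays limits the precision.

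The deposited values are on the log2 scale, 1 value per probe set and array, and the labels name GCRMA as the authors' method of background correction, normalization and summary. Its version and the software around it are not given in the sources used here. The 15 columns ran from 0.51 to 16.13, with array medians between 3.21 and 3.46. Between 33.8 and 35.0% of the probe sets exceeded 5 on each array, and 5 served as the limit between signal and background. Values were used as deposited, with no further normalization in the comparisons of the report.

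Of the 45101 probe sets, 34945 were annotated to 1 gene, 932 to several genes and 9160 to no gene, and 64 were control probe sets. The unit was the gene, read from the single-gene probe set with the highest mean over all 15 arrays. A gene was tested if that probe set exceeded 5 in at least 3 of the 15 arrays, which kept 9663 of 18193 genes. Probe sets with several genes or none were left out of the comparisons, because no gene could be named, and were tested separately. 1 of the 13 genes to be named at all events is not reported here.

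Differences were tested with limma 3.58.1 in R 4.3.3, using a means model over the 5 ages, empirical Bayes moderation with a trend in the prior variance and 10 residual degrees of freedom. The median prior added 4.85 degrees of freedom. Contrasts were P40 minus P7 and the 4 steps between neighbouring ages, and the moderated F test covered any difference between ages. All tests were two-sided, with Benjamini-Hochberg adjustment over the 9663 genes within each contrast, and a call is an adjusted p under 0.05. SE is the moderated standard error of a log2 difference, and ± gives the SD over 3 arrays. A fold is given only where both means exceed 5. Where all 3 arrays of an age lay at or under 5, the fold is a bound, the mean of the other age against 5. Otherwise levels are given. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

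The contrasts, the lists, the rule for naming genes and most of the other settings tried were set before the data were examined. The rule named, among called genes whose arrays did not overlap between P7 and P40, the 10 largest rises and the 10 largest falls with means over 5 at both ages. It added the 5 smallest adjusted p in each direction among genes that crossed the limit of 5 on all arrays. In each step it named the 3 largest rises and 3 largest falls, and in each list the 2 called members with the smallest adjusted p in each direction. The genes Pvalb, Gad1, Gad2, Slc32a1, Kcnc1, Kcnc2, Scn1a, Kcnk3, Slc12a5, Slc17a7, Sst and Vip were named whatever their values. Any other gene named was chosen after its values were seen.

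The 22 functional lists were voltage-gated potassium channels; leak, inward-rectifier and calcium-activated potassium channels; voltage-gated sodium and HCN channels; voltage-gated calcium channels; GABA synthesis, packaging and uptake; chloride transport; GABA receptor subunits and glutamate receptor subunits. Further lists were calcium-binding proteins, synaptic vesicle release machinery, immature neuron and neurite growth, axon guidance ligands and receptors, neurofilament and axon structure, and perineuronal net and extracellular matrix. The remainder were oxidative phosphorylation, glycolysis and tricarboxylic acid cycle, interneuron transcription factors, trophic factor signalling, sterol biosynthesis, immediate early and dissociation response, cytosolic ribosomal proteins and chromatin regulators. The 10 marker lists covered parvalbumin interneurons, other interneuron classes, excitatory neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelial and mural cells, blood and cycling progenitors. Of 744 symbols written, 671 were on the array under a single gene. Lists with at least 3 tested members, 27 in all, were tested with limma's camera for P40 minus P7, with a preset correlation of 0.01 between genes and again with an estimated correlation. Their p was adjusted over the 27 lists.

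Of 32 alternatives, each result was recomputed under those that apply to it, at most 31. Those set in advance were quantile normalization, a median shift per array, no filter, a filter at 7, values under 5 set to 5, a constant prior variance, the mean of a gene's probe sets, array weights, and the number of cells picked as a covariate. The beta-actin 3′ minus 5′ difference as a covariate, the replicate number as a block, fits on the 6 arrays compared, calls of at least 2-fold, an estimated correlation for the lists, and each array left out in turn completed the plan. The median shift, called equal array medians below, equalized the medians of the tested genes, not those of all probe sets. Leaving out the 2 arrays without hybridization controls, a pair of arrays off their ages' means, or all 3 P25 arrays was chosen after seeing the data. With an array left out, an age kept 2 arrays and the spread was pooled over all ages. Without the 2 arrays lacking hybridization controls P15 kept 1 array, which was assumed to vary like the other ages.

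The analysis was tested on simulated data with the spread of these arrays, in 20 simulations of the P40 minus P7 contrast with 200 changed genes each. A 2-fold change was recovered in 21.2% of the changed genes and a 4-fold change in 72%, and 5.2% of the calls were false. None of the calls had the wrong direction (0). The simulation changed 200 of 9663 genes, whereas 4365 were called in the real contrast, and it drew noise independently for each gene. Its rates of recovery and of false calls therefore need not hold for the real arrays. The simulation was run 20 times after a first run on 1 simulated set. Correlations across arrays were tested by permuting arrays within ages, with all 7776 arrangements.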

Results

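Gene expression was measured on 15 arrays, from 3 mice at each of 5 postnatal ages: P7, P10, P15, P25 and P40. Each array holds RNA of 23 to 85 hand-picked G42 interneurons of the primary somatosensory cortex, with the fewest cells at P15, where 23 to 45 were picked. Pvalb, the calcium-binding protein that defines this cell class, read 3.62 ± 0.72 (SD, n = 3) on the log2 scale at P7 and 14.28 ± 0.20 at P40. Slc17a7, the vesicular glutamate transporter of excitatory neurons, stayed at background, at 2.59 ± 0.02 at P7 and 2.46 ± 0.04 at P40. Vip, a peptide of another interneuron class, also stayed there, at 2.78 ± 0.08 and 2.60 ± 0.03. Sst, likewise a peptide of another interneuron class, was high, at 11.53 ± 1.21 at P7 and 8.34 ± 5.76 at P40. Across genes, which are not independent replicates, the correlation between arrays of 1 age ran from 0.921 to 0.976, and between arrays of different ages from 0.764 to 0.967. The first principal component held 54.5% of the variance and the second 10%.

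Signs of RNA quality moved with age. The beta-actin 3′ minus 5′ difference, which is larger when the amplified RNA is shorter, was 5.77 ± 0.98 (SD, n = 3) at P7, 5.73 ± 0.37 at P10, 4.50 ± 1.29 at P15, 5.31 ± 0.68 at P25 and 3.93 ± 0.55 at P40. The 3′ beta-actin control read 12.19 ± 1.04 at P25 and 13.73 ± 0.33 at P40, and its lowest array was P25 replicate 2. Spiked hybridization controls read 2.57 and 2.51 on P15 replicates 2 and 3, and at least 10.59 on the other arrays. Those 2 arrays and the 3 P40 arrays also had the lowest medians over all probe sets, from 3.21 to 3.24, against 3.31 or more on the others. A technical difference shared by them cannot be told apart from age in comparisons with P40. P25 replicate 2 and P15 replicates 2 and 3 are named beside the results that depend on them.

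The comparison of P40 with P7 asks how far the transcripts of these neurons changed over the postnatal period. Pvalb was at least 622-fold higher at P40 (adjusted p = 3.1e-12). Sgpp2, a sphingosine-1-phosphate phosphatase, was at least 116-fold higher, and the G protein-coupled receptor Gpr83 at least 90.8-fold. Fbxo2, a ubiquitin ligase subunit, and Lrrc38, an auxiliary subunit of large-conductance potassium channels, were at least 45.7-fold and 20.1-fold higher. Aldoc, the brain form of aldolase, rose 85.6-fold, from 6.42 ± 0.87 to 12.84 ± 0.37 (SD, n = 3). The other large rises were Gm13629 (83.2-fold), Abhd3 (74.7-fold), the neurotrophin-3 receptor Ntrk3 (61.0-fold), the Ras exchange factor Rasgrf1 (56.9-fold), the sodium-calcium exchanger Slc24a2 (52.4-fold) and Cgrrf1 (47.4-fold). Ttc39b rose from 5.62 ± 2.14 to 11.44 ± 0.44, Sdcbp from 5.88 ± 2.06 to 11.57 ± 0.34 and Unc80 from 5.51 ± 2.10 to 11.19 ± 0.17, each with 1 P7 array under 5. The SE of these rises from Aldoc on ran from 0.30 to 0.79 on the log2 scale and their adjusted p from 1.2e-08 to 3.8e-05. Without P7 replicate 1 the log2 differences of Ttc39b, Sdcbp and Unc80 were 4.64, 6.82 and 6.73 in place of 5.82, 5.68 and 5.68, without P7 replicate 2 those of Ttc39b and Sdcbp were 6.72 and 4.81, and without P7 replicate 3 that of Unc80 was 4.63. The mean of probe sets gave 4.42 for Ttc39b, 3.37 for Sdcbp, whose other probe set gave 1.05, 4.30 for Ntrk3 and 6.98 for Rasgrf1 (5.93 and 5.83 as used).

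Sox11, a transcription factor of immature neurons, was 128-fold lower at P40, from 12.97 ± 0.63 to 5.97 ± 1.41 (SD, n = 3). Marcksl1 and Marcks, which bind actin at the membrane, fell by 6.64 and 5.41 on the log2 scale. The growth cone protein Gap43 was 81.1-fold lower, and Dcx, a microtubule protein of migrating neurons, 49.0-fold lower. D430019H16Rik (46.1-fold), C1qtnf12 (34.7-fold), Cplx2 (31.1-fold), Pdzd2 (29.6-fold) and Grm3 (29.1-fold) made up the rest of the 10 largest falls. Their SE ran from 0.35 to 0.76 and their adjusted p from 3.2e-08 to 4.6e-05. Without P40 replicate 1 the log2 differences were -6.19 for Sox11, -5.68 for Marcksl1, -4.60 for Marcks, -5.61 for Gap43, -4.76 for D430019H16Rik, -4.48 for C1qtnf12 and -4.11 for Cplx2. Without P40 replicate 2 they were -7.39, -6.54 and -5.88 for Marcksl1, D430019H16Rik and C1qtnf12, and without P40 replicate 3 -5.60 for Cplx2. The mean of probe sets gave -2.69 for Pdzd2, whose other probe set gave -0.49, -5.74 for Sox11, -5.32 for Marcksl1 and -6.73 for Dcx. Genes that went to background by P40 included Scn3a, the sodium channel of immature neurons, at least 23.5-fold lower, and Vcan, a matrix proteoglycan, at least 17.1-fold lower. Ndrg1, Rhobtb1 and the axon repellent Draxin were at least 11.8-fold, 9.60-fold and 7.84-fold lower.

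In all, 4365 of 9663 genes were called between P7 and P40 by limma, 2662 higher and 1703 lower at P40, and 3462 of them changed at least 2-fold. The median change among called genes was 1.52 in either direction. Of 126 named genes called here, the fold of 28 moved by over 1.5 times when some array was left out, and that of 26 with the mean of their probe sets. On all 3 arrays, 185 called genes went from at or under 5 to over 5, and 177 went the other way. The moderated F test called 4559 genes for any difference between ages. For called genes named in this comparison the 3 arrays of each age did not overlap, except for Calb1 and Uqcrb. The naming rule required this of the largest changes and chose the list members by small adjusted p, so it is no separate test. The median of all genes tested was 0.177 higher at P40. The share of calls that were higher, 61.0%, became 51.5% with quantile normalization and 49.4% with equal array medians over the tested genes. With the 3′ minus 5′ difference as a covariate 2652 genes were called, 1368 of them higher. Without a filter on dim genes 8295 were called, of which 3870 stayed at or under 5 at every age. Of those 3870 genes, 3765 were lower at P40.

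**Figure D1:**
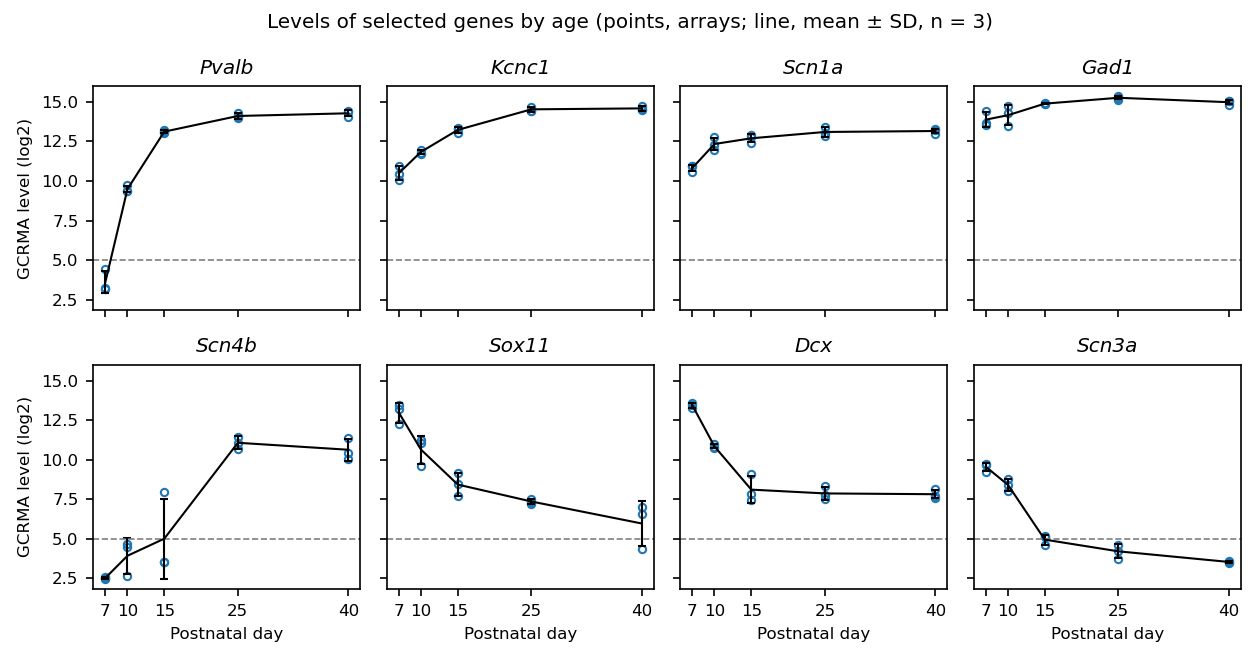
GCRMA level (log2) against postnatal day for 8 genes. Points are single arrays, the line joins means with SD (n = 3), and the dashed line marks 5, the limit to background. Pvalb climbed from 3.62 to 14.28 while Dcx went from 13.43 to 7.82.

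Ion channel genes moved both ways. Of 28 voltage-gated potassium channel genes tested, 13 rose, 7 fell and 8 did not pass (14 and 7 adjusted over the list alone). Kcnc1, which encodes the fast delayed rectifier Kv3.1, rose 17.0-fold (SE 0.19, adjusted p = 1.5e-09), and its relative Kcnc2 rose 2.79-fold (SE 0.21, adjusted p = 7.1e-05). Kcna1 rose 39.0-fold, while Kcns2 fell by 3.82 on the log2 scale and Kcnq5 fell 2.75-fold. The probe sets of Kcnc1 ran from 0.78 to 4.33 and their mean gave 3.06 in place of 4.09, and Kcns2 gave -3.20 and -4.48 without P40 replicates 1 and 2. The list was called higher (adjusted p = 0.028; adjusted p = 0.19 with an estimated correlation), and its call was lost without P7 replicate 2 (mean log2 difference 1.11 in place of 1.27). Of 12 leak, inward-rectifier and calcium-activated potassium channel genes, 4 rose and 1 fell (the same adjusted over the list alone), and the list was not called (adjusted p = 0.42). The acid-sensitive leak channel Kcnk3 rose 14.8-fold (SE 0.39, adjusted p = 2.5e-06), Kcnk1 rose 6.86-fold, Kcnj9 went from 4.74 ± 0.93 to 10.19 ± 0.13 and Kcnt2 was at least 9.92-fold lower.

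All 13 sodium and HCN channel genes tested changed, 7 upward and 6 downward (the same adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.90). Scn1a, the Nav1.1 channel, rose by 2.32 on the log2 scale (SE 0.22, adjusted p = 1.4e-06), Scn8a rose 4.01-fold, Scn2b rose 15.4-fold and Scn4b was at least 49.4-fold higher, while Scn2a fell 13.2-fold. Its mean difference of 0.15 became -0.07 with equal array medians, and another probe set of Scn2b had the opposite sign. The mean of probe sets gave log2 differences of 3.01 for Scn1a, 2.74 for Scn8a, 2.55 for Scn2b, -2.98 for Scn2a and -4.31 for Cacng4 (2.32, 2.00, 3.95, -3.72 and -6.56 as used). Of 14 voltage-gated calcium channel genes, 1 rose and 8 fell (the same adjusted over the list alone), and the list was called lower with both correlations (adjusted p = 0.0033; adjusted p = 0.029 with an estimated correlation). The list also holds auxiliary subunit genes of the Cacng and Cacnb families. Among these, Cacng4 was at least 34.9-fold lower and Cacnb4 rose 3.74-fold. The T-type channel Cacna1g went from 8.25 ± 0.20 to 3.81 ± 1.09 (log2 difference -4.45, and -5.06 without P40 replicate 2). Without a filter this list was not called (mean log2 difference -1.39 in place of -1.82).

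Genes of the inhibitory transmitter rose together. All 6 genes of GABA synthesis, packaging and uptake rose (6 and 0 adjusted over the list alone; adjusted p = 0.00091; adjusted p = 0.12 with an estimated correlation). Gad2 and Gad1, the GABA-synthesizing enzymes, rose 6.29-fold (SE 0.27, adjusted p = 2.8e-06) and 2.15-fold (SE 0.25, adjusted p = 0.0024). The vesicular transporter Slc32a1 rose 1.65-fold (SE 0.13, adjusted p = 0.00042) and the glutamine transporter Slc38a1 2.67-fold. Of 7 chloride transport genes 3 rose and 0 fell (the same adjusted over the list alone), with no call for the list (adjusted p = 0.37). Slc12a5, the chloride extruder KCC2, rose 3.52-fold (SE 0.31, adjusted p = 0.00027) and Clcn6 1.94-fold. Of 9 GABA receptor subunit genes 4 rose and 2 fell (the same adjusted over the list alone; adjusted p = 0.78). Gabrb2 and Gabrd rose 3.44-fold and 5.58-fold, Gabra5 fell 7.27-fold, and Gabra2 went from 7.26 ± 0.54 to 4.61 ± 0.75. The other probe set of Gad1 gave a log2 difference of 4.98, against 1.10 for the one used, and the mean of probe sets gave 3.04 for Gad1 and 3.58 for Gad2 (2.65 as used). The calls of Gad1 and Clcn6 were lost with the 3′ minus 5′ difference as a covariate (log2 differences 0.83 and 0.73).

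Of 16 glutamate receptor genes, 3 rose and 7 fell (3 and 8 adjusted over the list alone). The AMPA receptor subunits Gria4 and Gria3 rose 3.19-fold and 2.03-fold, and the metabotropic receptor Grm3 and the kainate receptor Grik3 fell, the latter 3.23-fold. The list was called lower (adjusted p = 0.032; adjusted p = 0.09 with an estimated correlation), a call that was lost without P7 replicate 3 (mean log2 difference -0.77), with cells picked or the 3′ minus 5′ difference as a covariate, and without a filter. With the mean of its probe sets Gria3 was not called (log2 difference 0.90). Of 13 calcium-binding protein genes 5 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.42). Ncs1, a neuronal calcium sensor, rose by 2.14 on the log2 scale (SE 0.40). Calb1 fell by 5.17 on the log2 scale (SE 1.40, adjusted p = 0.0076), with 5.65 ± 4.13 at P40, and its call was lost with array weights or the 3′ minus 5′ covariate. Without P40 replicates 1, 2 or 3 the difference of Calb1 was -3.87, -4.09 or -7.55, and with the mean of its probe sets -3.36.

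Of 38 genes of the vesicle release machinery, 24 rose, 6 fell and 8 did not pass (the same adjusted over the list alone). The vesicle proteins Vamp1 and Syt2, both abundant in fast inhibitory terminals, rose 37.1-fold and 36.1-fold, Cplx2 fell 31.1-fold and the priming factor Unc13c was at least 4.71-fold lower. The list was called higher (adjusted p = 0.0041; adjusted p = 0.21 with an estimated correlation). Of 16 neurofilament and axon structure genes, 12 rose and 0 fell (the same adjusted over the list alone; adjusted p = 0.00027; adjusted p = 0.09 with an estimated correlation). Nefh rose 22.5-fold and Nefm was at least 39.6-fold higher. Of 12 genes of the perineuronal net and extracellular matrix, 4 rose and 4 fell (the same adjusted over the list alone; adjusted p = 0.78). The link proteins Hapln4 and Hapln1 were at least 78.6-fold and 21.4-fold higher, and Ncan, like Vcan a proteoglycan, fell 8.75-fold. The mean of probe sets gave log2 differences of 3.73 for Syt2 and 3.12 for Hapln1 (5.17 and 5.66 as used), and Cplx2 gave -4.11 and -5.60 without P40 replicates 1 and 3.

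Growth and guidance genes fell. Of 32 genes of immature neurons and neurite growth, 26 fell and 1 rose (27 and 2 adjusted over the list alone; adjusted p = 8.9e-13; adjusted p = 0.029 with an estimated correlation). Cd24a, a surface protein of young neurons, went from 12.53 ± 0.20 to 3.87 ± 1.01, and the one rise was Cntn2, an axonal adhesion molecule, at 3.10-fold. Of 35 axon guidance genes, 18 fell and 3 rose (19 and 3 adjusted over the list alone; adjusted p = 2e-05; adjusted p = 0.029 with an estimated correlation). Sema3a, a secreted repellent, fell 17.4-fold and the ephrin receptor Ephb1 was at least 8.84-fold lower, while Plxnc1 rose 4.81-fold and Sema3e 1.76-fold. Sema3e was not called without P7 replicate 2, P7 replicate 3 or P40 replicate 1 (log2 differences from 0.65 to 0.74), nor with equal array medians, and Plxnc1, at 2.27, gave 2.89 without P7 replicate 1 and was not called with the 3′ minus 5′ covariate. Ephb1 gave -5.31 without P40 replicate 3 in place of -4.64, and the mean of probe sets gave -7.20 for Cd24a and -2.29 for Npas3 (-8.66 and -3.44 as used). Of 18 interneuron transcription factors, 8 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.0033; adjusted p = 0.029 with an estimated correlation). Npas3 fell 10.8-fold and Dlx2 5.30-fold, and Esrrg rose 4.03-fold. Without a filter neither axon guidance genes (mean log2 difference -1.02) nor the transcription factors (-0.66) were called.

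Of 56 oxidative phosphorylation genes, 30 rose and 2 fell (32 and 2 adjusted over the list alone; adjusted p = 0.00028; adjusted p = 0.13 with an estimated correlation). Sdha, of complex II, rose 2.78-fold and Ndufa2, of complex I, rose 1.81-fold. Cox7c fell by 1.66 on the log2 scale, a call lost without P7 replicate 1, P7 replicate 3, P40 replicate 1 or P40 replicate 3 (log2 differences from -1.67 to -1.15). Uqcrb fell by 0.31 on the log2 scale and had another probe set of opposite sign. Its call was lost under 9 other settings and without P7 replicates 2 or 3, P10 replicate 2, P15 replicate 3, P25 replicates 1, 2 or 3, or P40 replicates 1 or 2 (log2 differences from -0.31 to -0.23). Of 27 genes of glycolysis and the tricarboxylic acid cycle, 18 rose and 3 fell (21 and 3 adjusted over the list alone; adjusted p = 0.00028; adjusted p = 0.13 with an estimated correlation). The neuronal enolase Eno2 rose 4.23-fold and the lactate dehydrogenase Ldha fell 4.82-fold. Cs, citrate synthase, fell by 0.41 on the log2 scale, but its probe sets ran from -0.41 to 0.50 and their mean gave 0.06.

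Of 18 sterol biosynthesis genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone; adjusted p = 5.9e-07; adjusted p = 0.029 with an estimated correlation). Fdft1, squalene synthase, fell 12.2-fold and Mvd was at least 20.4-fold lower. Of 28 cytosolic ribosomal protein genes, 20 fell and 0 rose (the same adjusted over the list alone; adjusted p = 4.1e-08; adjusted p = 0.029 with an estimated correlation), among them Rps18 (2.46-fold) and Rpl35 (1.79-fold). Of 31 chromatin regulators, 14 fell and 2 rose (14 and 3 adjusted over the list alone; adjusted p = 0.0028; adjusted p = 0.029 with an estimated correlation), a call lost without a filter (mean log2 difference -0.67). The DNA methyltransferases Dnmt1 and Dnmt3a fell by 2.02 on the log2 scale and 3.83-fold, the deacetylase Hdac11 rose 2.69-fold, and Mbd2 went from 4.74 ± 0.46 to 7.07 ± 0.41. Of 14 trophic factor genes, 4 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.78), with Gfra1, a GDNF receptor, at least 7.24-fold higher and Igf1 lower by a log2 difference of -4.27. Igf1 gave -3.31 and -4.99 without P40 replicates 1 and 3, and the mean of probe sets gave -3.15 for Igf1 and -2.91 for Fdft1 (-3.61 as used). Dnmt1 gave from -0.88 to -0.76 without P7 replicates 2 or 3, P10 replicates 1 or 2 or P25 replicate 2, where another of its probe sets had the highest mean.

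Of 22 immediate early and dissociation response genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted p = 0.00037; adjusted p = 0.20 with an estimated correlation). Klf6 fell 16.2-fold and Klf4 was at least 43.0-fold lower, and the heat shock genes Hspa1a and Hsp90aa1 rose 2.97-fold and 1.38-fold. Hspa1a was not called without P7 replicate 3, P40 replicate 2 or P40 replicate 3 (log2 differences from 0.93 to 1.5). Nor was it called with cells picked or the 3′ minus 5′ difference as a covariate (1.31 and 1.35). Hsp90aa1 was not called without P7 replicate 3 (log2 difference 0.28) or under 8 other settings (from 0.24 to 0.47), among them equal array medians and both covariates. Klf4 gave -7.28 without P7 replicate 3 and -5.41 with the mean of its probe sets, in place of -6.64. In all, 16 of 27 lists were called, 7 higher and 9 lower, and 8 with an estimated correlation, 1 higher and 7 lower. With the preset correlation, the 9 groupings that mix P7 with P40 arrays called 6 to 11 lists. The beta-actin 3′ minus 5′ difference moved over the same interval as these lists, from 5.77 to 3.93.

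**Figure D2:**
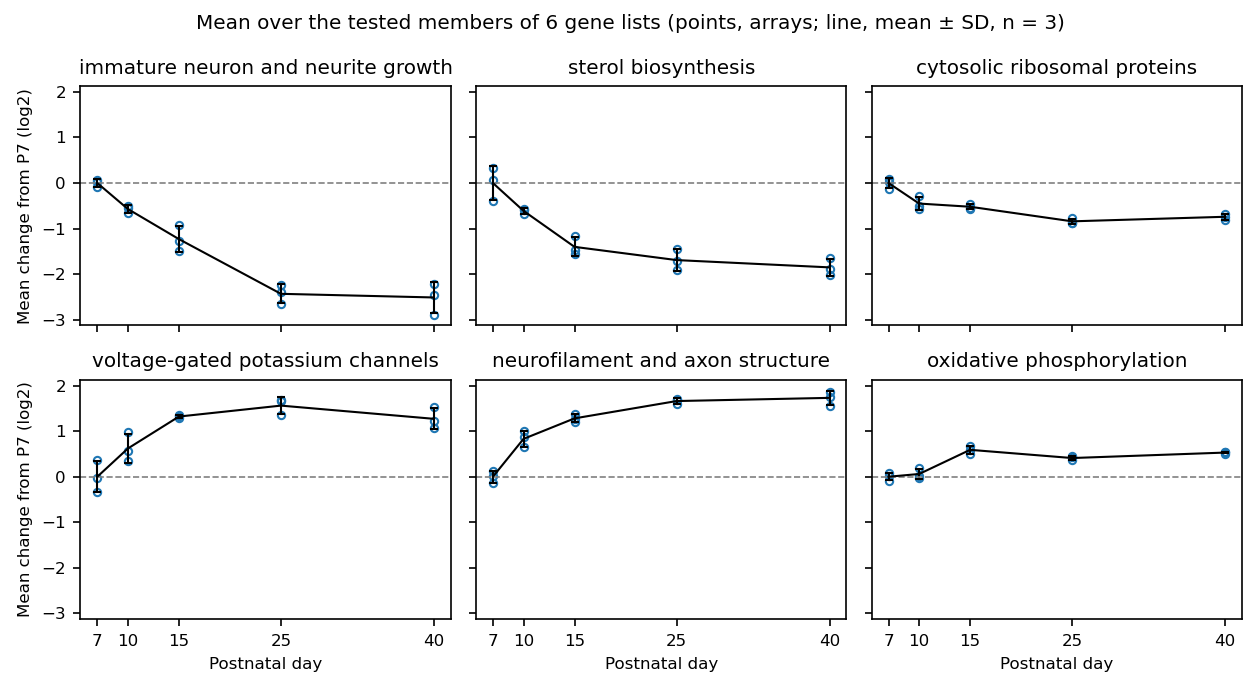
Mean change from P7 (log2) of the tested members of 6 gene lists against postnatal day. Points are arrays and the line joins means with SD (n = 3). Immature neuron and neurite growth genes reached -2.51 at P40 and neurofilament and axon structure genes 1.73.

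Of 17 parvalbumin interneuron markers, 12 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 2e-04; adjusted p = 0.029 with an estimated correlation), and 13 of the 17 also stand in another list. Lhx6, a transcription factor of this lineage, fell 1.78-fold and Nxph1 1.59-fold, with 1 Nxph1 probe set of opposite sign. Of 8 markers of other interneuron classes, 2 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.85). Its median was 0.27 while its mean was -0.49 and the test pointed down, and without P40 replicate 1 the mean was 0.35. Cck rose 11.7-fold and Nos1 was at least 1.76-fold higher, while Reln fell by 2.70 on the log2 scale (-1.93 and -3.35 without P40 replicates 1 and 3) and Chodl was at least 18.2-fold lower. The call of Nos1 was lost with the 3′ minus 5′ covariate. Sst, a peptide of another interneuron class, read 11.53 ± 1.21 at P7 and 8.34 ± 5.76 at P40 and was not called (log2 difference -3.19, SE 1.88, adjusted p = 0.18). Its difference was 0.11 without P40 replicate 1, and -5.15, which passed the test, without P40 replicate 3.

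Of 8 astrocyte markers, 2 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.86), with a median of -0.33, a mean of 0.56 and a test that pointed down. Besides Aldoc, S100b went from 3.46 ± 0.11 to 5.96 ± 2.21, a call lost without P7 replicate 2, P40 replicate 1 or P40 replicate 3 (log2 differences from 1.39 to 2.52), and its difference was 3.61 without P40 replicate 2. The call of S100b was also lost under 5 other settings (from 1.37 to 2.69), among them values under 5 set to 5 and both covariates. The glutamate transporter Slc1a2 went from 4.85 ± 0.95 to 3.5 ± 0.01 with both means under 5. Its call was lost without P7 replicate 3 (log2 difference -0.88), with values under 5 set to 5, with cells picked or the 3′ minus 5′ difference as a covariate and from the 6 arrays alone (from -1.35 to -0.26). Of 4 oligodendrocyte markers, 1 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.84), with a median of -0.08, a mean of 0.67 and a test that pointed down. Ugt8a was at least 4.50-fold higher (log2 difference 4.49, and 3.75 and 5.19 without P40 replicates 1 and 2) and Cnp fell 3.14-fold. Of 4 excitatory neuron markers, Camk2a and Rasgrf2 rose 4.24-fold and by 3.64 on the log2 scale and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.37). Rasgrf2 gave 4.41 without P7 replicate 1.

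Too few members of the remaining marker lists were measured for a test. The microglial receptor Csf1r, the 1 member tested, went from 5.11 ± 0.92 to 3.28 ± 0.07 and was not called with values under 5 set to 5. Its call was also lost with the 3′ minus 5′ difference as a covariate (log2 difference -1.22 in place of -1.83). The 1 oligodendrocyte precursor marker and the 2 endothelial and mural markers were not called, and 0 of 5 blood markers passed the filter. Of 2 cycling progenitor markers, the centromere protein Cenpa went from 5.11 ± 1.17, with 2 of the 3 P7 arrays under 5, to 9.77 ± 0.44 and the intermediate filament Vim was at least 2.78-fold lower. The log2 difference of Cenpa, 4.66, was 5.33 without P7 replicate 1. For called genes, 2183 of 2645 further probe sets of the same gene (82.5%) moved the same way.

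The step from P7 to P10 shows which changes came early. Pvalb was at least 22.4-fold higher at P10 (adjusted p = 1.9e-08). The calcineurin-like protein Tesc rose 15.1-fold (SE 0.45, adjusted p = 0.00015), Rasgrf1 14.3-fold (SE 0.35, adjusted p = 2.1e-05) and the formin Fmn1 12.1-fold (SE 0.38, adjusted p = 8.7e-05). Mex3a, an RNA-binding protein, fell 36.5-fold (SE 0.38, adjusted p = 1.5e-06), Chodl 10.3-fold (SE 0.41, adjusted p = 0.00025) and the proteoglycan Sdc1 by 3.33 on the log2 scale (SE 0.55, adjusted p = 0.0025). Gad2 rose 4.16-fold, Scn1a 2.83-fold, Kcnc1 2.53-fold and Slc32a1 1.48-fold. Of 16 neurofilament and axon structure genes 4 rose, including Nefh (6.82-fold), and of 17 parvalbumin interneuron markers 8 rose. In the matrix list 4 of 12 genes rose and Vcan was at least 17.1-fold lower. Among astrocyte markers Slc1a2 went from 4.85 ± 0.95 to 8.44 ± 0.13 (adjusted p = 0.00015). Sdc1 gave -3.96 and -2.51 without P10 replicates 1 and 2, and the mean of probe sets gave 2.11 for Tesc and -4.12 for Mex3a (3.92 and -5.19 as used). The step called 348 genes, 229 higher and 119 lower. Fewer, 43, were called from the 6 arrays alone, where Chodl and Sdc1 were not called at the same log2 differences (-3.37 and -3.33), 208 without P7 replicate 2, 195 without P10 replicate 2, and 216 without P7 replicate 1 and P10 replicate 3.

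The step from P10 to P15 asks what changed in the second postnatal week. Of 56 oxidative phosphorylation genes 22 rose and 0 fell, and of 27 glycolysis and tricarboxylic acid cycle genes 13 rose and 0 fell, but with equal array medians 7 and 8 rose. Gpr83 rose by 3.97 on the log2 scale (SE 0.36, adjusted p = 2.4e-05; 3.14 with another probe set, which had the highest mean without P7 replicate 3 or P25 replicates 1, 2 or 3), Pvalb 12.4-fold (SE 0.28, adjusted p = 5.4e-06) and the tropomyosin Tpm2 11.4-fold (SE 0.43, adjusted p = 0.00055). Tpm2 gave 1.99 with the mean of its probe sets (3.51 as used). Cd24a fell 21.2-fold (SE 0.62, adjusted p = 0.0012), the nuclear RNA Malat1 12.7-fold (SE 0.94, adjusted p = 0.026) and Fkbp9 11.3-fold (SE 0.99, adjusted p = 0.036). Kcnc1 rose 2.63-fold, Kcnk3 2.84-fold and Kcnc2 1.98-fold. Of 18 sterol genes 6 fell, including Mvd (5.23-fold), and of 14 calcium channel genes 6 fell. The step called 1098 genes, 828 higher and 270 lower, and the median of all genes was 0.205 higher at P15. The share that was higher, 75.4%, became 57.7% with quantile normalization and 47.8% with equal array medians over the tested genes.

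P15 was the age with the fewest cells and 2 arrays without hybridization controls. Without those 2 arrays P15 kept 1 array, whose spread was taken from the other ages, and 32 genes were called, with 0 of the oxidative phosphorylation and glycolysis and tricarboxylic acid cycle genes and 1 sterol gene. Cd24a, Malat1 and Fkbp9 were not called there, with log2 differences of -3.28, -1.69 and -1.76 in place of -4.41, -3.67 and -3.49. The count was 357 without P10 replicate 1, 345 without P10 replicate 2, 1905 without P10 replicate 3, 150 without P15 replicate 2 and 308 without P15 replicate 3. It was 24 with cells picked as a covariate, 150 with the 3′ minus 5′ covariate, 53 from the 6 arrays alone, 530 without a filter and 2955 with array weights. Cells picked did not overlap between P10 (47 to 72) and P15 (23 to 45), so that covariate is partly tied to age. The array weights were 1.14 and 2.13 on the 2 P15 arrays without hybridization controls and 0.53 on P15 replicate 1. Malat1 and Fkbp9 were also not called without P10 replicate 1, P10 replicate 2, P15 replicate 2 or P15 replicate 3, with log2 differences from -3.51 to -3.10 and from -3.57 to -2.96. Neither was called without a filter, with cells picked or the 3′ minus 5′ difference as a covariate or from the 6 arrays alone (from -3.67 to -2.22 and from -3.76 to -2.58), nor was Malat1 with the mean of its probe sets (-1.77) or Cd24a with cells picked as a covariate (-4.46). Without P15 replicate 1 Malat1 and Fkbp9 gave -4.66 and -4.36, Malat1 gave -4.40 without P10 replicate 3, and Cd24a gave -2.98 with the mean of its probe sets. Other probe sets of Malat1 moved the opposite way between P7 and P40.

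The step from P15 to P25 covers the weeks around weaning. Of 32 genes of immature neurons and neurite growth 15 fell and 0 rose, among them Gap43, 19.0-fold lower (SE 0.76, adjusted p = 0.0054), and Marcksl1, 14.7-fold lower (SE 0.60, adjusted p = 0.0021). Gnb4, a G protein subunit, fell 19.8-fold (SE 0.79, adjusted p = 0.0066). Scn4b, the sodium channel subunit of resurgent current, rose from 5.01 ± 2.52 to 11.07 ± 0.40 (SE 0.89, adjusted p = 0.0016), with P15 arrays at 7.93, 3.56 and 3.55. Its log2 difference of 6.05 was 7.51 without P15 replicate 1, 5.33 without P15 replicate 2 and 5.32 without P15 replicate 3. Apol8 rose 10.4-fold (SE 0.51, adjusted p = 0.0018) and the linker histone H1f2 12.5-fold (SE 0.76, adjusted p = 0.014). Kcnc1 rose 2.47-fold and Kcnk3 2.73-fold, Gfra1 was at least 7.53-fold higher, and of 16 neurofilament and axon structure genes 3 rose.

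That step called 470 genes, 229 higher and 241 lower. Without the arrays lacking hybridization controls, which leaves 1 array at P15, 61 were called, 3 of the 32 growth genes fell, and Gap43, Marcksl1, Gnb4, Scn4b and H1f2 were not called. Against that 1 array the log2 differences were -3.83 for Marcksl1, -4.64 for Gnb4, -3.17 for Gap43, 3.14 for Scn4b and 1.49 for H1f2. The count was 226 without P15 replicate 2, 158 without P15 replicate 3, 274 without P25 replicate 1, 176 without P25 replicate 2 and 277 without P25 replicate 3. H1f2 was also not called without P15 replicate 2, P15 replicate 3, P25 replicate 1 or P25 replicate 2 (log2 differences from 2.86 to 3.64), and gave 4.73 without P15 replicate 1. Apol8, at 3.38, gave 4.0 without P15 replicate 2, Gap43, at -4.25, gave -5.25 without P25 replicate 1, and Gnb4, at -4.31, gave -4.98 and -3.57 without P25 replicates 1 and 3. With the mean of probe sets, Marcksl1 gave -3.18 and Gnb4 -3.54 (-3.88 and -4.31 as used). With cells picked and with the 3′ minus 5′ difference as covariates, 190 and 310 genes were called, and 1622 with array weights. Those weights were higher on the P15 arrays without hybridization controls than on P15 replicate 1. At P25 the 3′ beta-actin control was at its lowest, and the glial transcripts Mbp and Mobp rose from 8.22 ± 0.95 and 3.14 ± 0.38 to 11.21 ± 0.63 and 7.47 ± 1.03.

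Between P25 and P40, of the genes named whatever their values, none was called (0). Prkaa2, a catalytic subunit of AMP-activated kinase, rose by 4.01 on the log2 scale (SE 0.57, adjusted p = 0.0076), Smc6 11.1-fold (SE 0.57, adjusted p = 0.023) and Nbeal1 11.1-fold (SE 0.60, adjusted p = 0.025), from levels of 6.16 ± 1.65, 6.70 ± 1.14 and 5.89 ± 1.02 at P25. The myelin protein Mbp fell 25.6-fold (SE 0.62, adjusted p = 0.0049), from 11.21 ± 0.63 to 6.52 ± 1.37. Marcks fell 6.06-fold (SE 0.56, adjusted p = 0.049) and Flywch2 4.28-fold (SE 0.43, adjusted p = 0.041). Mbp had not been called between P7 and P40 (log2 difference -0.18, SE 0.62, adjusted p = 0.83), nor had Prkaa2 (0.73, SE 0.57, adjusted p = 0.31). With the 3′ minus 5′ difference as a covariate Prkaa2 was not called (log2 difference 3.39). From the 6 arrays alone Prkaa2, Smc6, Nbeal1, Mbp, Marcks and Flywch2 were not called, with 4.01 for Prkaa2 and -4.68 for Mbp. Prkaa2 gave 3.22 and 4.86 without P25 replicates 2 and 3, and the mean of probe sets gave 2.21 for Prkaa2, -3.48 for Mbp and -1.78 for Marcks.

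That step called 65 genes, 39 higher and 26 lower, and 1110 had an unadjusted p under 0.05. With array weights it called 1001. It called 37 without P7 replicate 2, 29 without P10 replicate 2, 41 without P15 replicate 2, 7 without P25 replicate 1, 3 without P25 replicate 2, 142 without P25 replicate 3, 6 without P40 replicate 1, 42 without P40 replicate 2 and 9 without P40 replicate 3. With the mean of their probe sets, the log2 differences of Smc6 and Nbeal1 were 0.67 and 1.52, and neither was called. They were also not called without P25 replicate 1, P25 replicate 2, P40 replicate 1 or P40 replicate 3, with log2 differences from 2.86 to 3.59 and from 2.96 to 3.48. Marcks lost its call in 14 of the 15 fits with 1 array left out (log2 differences from -3.04 to -1.79). Flywch2 lost its call in 9 of them, without P7 replicates 2 or 3, P10 replicate 2, P15 replicates 2 or 3, P25 replicates 1 or 2, or P40 replicates 1 or 3 (from -2.10 to -1.61). Flywch2 gave -2.80 without P40 replicate 2. Mbp lost its call without P25 replicate 2 (log2 difference -4.50) and gave -3.96 and -5.32 without P40 replicates 1 and 3, and Smc6 and Mbp had probe sets of opposite sign between P7 and P40.

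**Figure D3:**
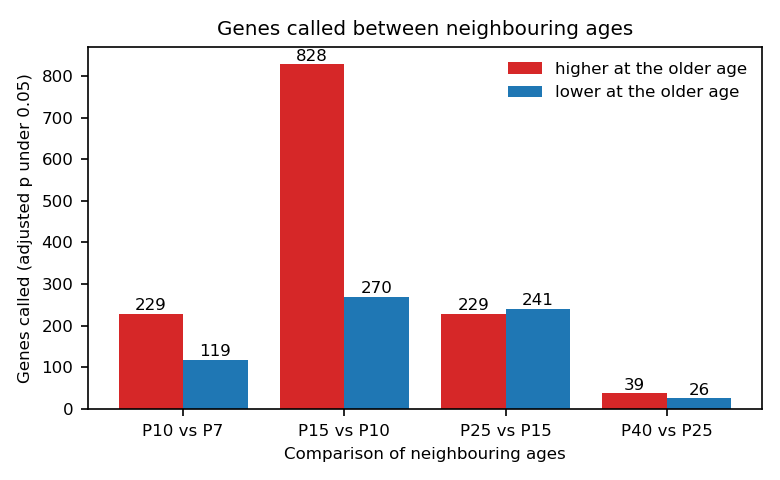
Number of genes called (adjusted p under 0.05) between neighbouring ages. Bars give genes higher and lower at the older age, with 828 and 270 from P10 to P15 and 39 and 26 from P25 to P40.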

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

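The splits of the arrays named here were set before their results were seen, and the tests of probe sets outside the gene table and of control probe sets were chosen after.

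Probe sets without a single named gene, left out of the comparisons, also differed between ages. Of 1781 tested, 639 were called between P7 and P40 (35.9%), 345 higher and 294 lower at P40. No explanation was tested for them. Spiked hybridization controls, which no comparison used, read between 10.59 and 13.58 on 13 arrays, and 2.57 and 2.51 on P15 replicates 2 and 3. Why these 2 arrays differ is not given in the sources used here, and no biological explanation applies to a spiked control.

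Other splits of the same arrays were tested for each count. For the age effect, 1 of 100 splits, the real one, called as many genes (4559, highest other 3385), so chance is excluded at a share under 0.05. For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. There the real split and the highest other called 4365 and 0 genes for P40 against P7, 348 and 194 for P10 against P7, 1098 and 3 for P15 against P10, 470 and 1 for P25 against P15, and 65 and 1 for P40 against P25. In each of these comparisons 1 split, the real one, reached its own count. The other splits mix the 2 ages, so an age difference widens their spread, and their counts give no rate of false calls. The split with 194 genes set P7 replicate 1, P10 replicate 2 and P10 replicate 3 against the others. For the gene lists the real split called 16 and the highest other 11, again with 1 split reaching 16 and too few splits for a share under 0.05.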

How the results depend on the processing

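Leaving out the 2 arrays without hybridization controls, 2 arrays off their ages' means (P7 replicate 1 and P10 replicate 3) or all 3 P25 arrays was chosen after seeing the data. The other alternatives were set before. Of 126 named genes called between P7 and P40, 104 kept their direction and their call under every alternative that could be run for them, of 24 results named for a step 8 did, and of 16 called lists 4 did. The cause was not tested except where given. Without a filter, 8295 genes were called for P40 against P7 (5523 lower), 530 for P15 against P10 and 2998 for P40 against P25. Of these, 3870 and 2601 in the first and last stayed at or under 5 at every age, with median differences of 0.16 and 0.11 in size. Differences within the background make up that part. Nearly all of them, 3765 and 2586, were lower at P40. With the 3′ minus 5′ difference as a covariate, P40 against P7 called 2652 (1368 higher), P15 against P10 150, P25 against P15 310 and P40 against P25 12. With cells picked as a covariate, P15 against P10 called 24 and P25 against P15 190. Cells picked at P15 (23 to 45) did not overlap with P10 (47 to 72) or P25 (48 to 55). In both steps this covariate is therefore partly tied to age. Array weights gave 2955, 1622 and 1001 for the 3 later steps. The first and second of these counts lean on P15 replicates 2 and 3, with weights of 1.14 and 2.13 against 0.53 for P15 replicate 1. From the 6 arrays compared alone, with fewer residual degrees of freedom, 43 were called for P10 against P7, 53 for P15 against P10 and 9 for P40 against P25. The median shift and the mean of probe sets gave 40 and 25 for P40 against P25. The mean of probe sets also turned Cs from -0.41 to 0.06. An estimated correlation left 8 of 16 lists called. Without the arrays lacking hybridization controls, 32 were called for P15 against P10, 61 for P25 against P15 and 35 for P40 against P25. The first and second of these compare 1 P15 array, assumed to vary like the other ages. Without the 2 arrays off their ages' means it was 216 for P10 against P7 and 2274 for P15 against P10, and without the P25 arrays 729 for P15 against P10. With 1 array left out in turn, counts ran from 195 to 375 for P10 against P7, from 150 to 1905 for P15 against P10, from 158 to 540 for P25 against P15 and from 3 to 142 for P40 against P25. For P40 against P7 they ran from 3489 to 4526, for the age effect from 3913 to 4864 and for the lists from 15 to 16. The separate counts of higher and lower genes in the 4 steps also moved under many of these alternatives, and were left out here only after that was seen. With 33.8 to 35.0% of probe sets over 5 on each array, changes among the remaining probe sets were not measured.

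The replicate numbers do not pair the arrays. With the replicate number as a block, P15 against P10 called 727 and P40 against P25 16, and P40 against P7 called 4159.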

Other observations

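The tests of P25 replicate 2, of 3′ bias, of handling, of glial cells, of the number of cells and of the maturity of arrays were chosen only after the results were seen. The genes of the next paragraph were chosen after their values were seen.

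Further genes moved at single steps. Kcng4, a modifying potassium channel subunit, read 2.15 ± 0.02 (SD, n = 3) at P7, 2.13 ± 0.01 at P10, 2.11 ± 0.05 at P15, 8.14 ± 1.18 at P25 and 7.71 ± 0.36 at P40. Ryr1, a calcium release channel, read 2.48 ± 0.08 and 2.51 ± 0.07 at P7 and P10, and 6.80 ± 0.21, 7.69 ± 0.30 and 5.93 ± 0.66 at the later ages. The peptide precursor Cartpt read 1.70 ± 0.03 at P7, 6.53, 1.73 and 1.73 on the P10 arrays and 10.29 ± 1.18 at P15. Malat1 read 12.16 ± 1.33 at P10, 8.49 ± 1.71 at P15 and 11.60 ± 0.36 at P40. On P40 replicate 1, Sst read 1.72 and the stress peptide Crh 4.97, against 9.20 or more for Sst on every other array. Calb1 read 3.04 and 3.49 on P40 replicates 1 and 2 and 10.41 on replicate 3. On P10 replicate 3 the Y-linked gene Eif2s3y read 3.63, against 7.65 or more on the other arrays. Kdm5d, also Y-linked, read 2.71 there, against 5.22 or more on the others. Y-linked Uty, near background, read 4.51 there and from 4.20 to 5.22 on the others.

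At P25, 45 genes were lower than at both P15 and P40 by at least 1 on the log2 scale, among them Timp2 (12.47, 9.43 and 12.05), Zeb2 (11.86, 9.56 and 12), Gsk3b (11.55, 9.68 and 11.93) and Actb (13.35, 11.48 and 13.35), and 17 were higher, by a definition set after a first count was seen. Of 100 splits of the 9 arrays 1, the real one, gave 45 genes (highest other 16), a share under 0.05. The mixed splits also carry the other differences between P15, P25 and P40. They therefore cannot exclude chance for low values at P25 alone. A first test of P25 replicate 2 as the source left 7 of the 45 genes without it (10 without replicate 1, 85 without replicate 3), as that source predicts, although the median estimate moved only from -1.84 (SE 0.38) to -1.55 (SE 0.39). It was replaced by a test on held-out arrays, with 25 genes chosen on P25 replicate 2, where their median was -3.01. On the mean of P25 replicates 1 and 3 they were lower by a median of -1.35 (quartiles -1.78 and -0.91, 25 of 25 below 0). That argues against replicate 2 alone, although the fall was smaller there. The 45 genes were higher at P10 than at P25 by a median of 2.09 (quartiles 1.44 and 3.11), where the 3′ minus 5′ difference was 5.73 against 5.31. They were chosen for low P25 values, which this comparison uses again, and Actb, whose controls give the 3′ minus 5′ difference, is among them. With the 3′ minus 5′ covariate 13 genes were lower, 12 of them shared, so 3′ bias stays undecided. Shared handling of the P25 arrays cannot be told apart from age, since runs and dates of the arrays are not given in the sources used here (34 genes had all 3 P25 arrays below all 6 others), and a biological difference at P25 stays open as untested.

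Some glial transcripts were higher at P10 or P25 than at neighbouring ages: Mbp and Mobp at P25 (11.21 ± 0.63 and 7.47 ± 1.03), Slc1a2 at P10 (8.44 ± 0.13) and P25 (6.86 ± 0.45), and Gja1 at P10 (6.94 ± 3.2). Of 8 other oligodendrocyte markers, 1 (Cnp, 9.79 against 9.13 at its highest neighbour) met the test for whole oligodendrocytes at P25, and 6 read under 5. Cnp was higher still at P7 (10.75 ± 0.23). Of 10 other astrocyte markers, 1 (Glul, 10.50 against 10.44) met the test for whole astrocytes at P10, and 2 (Glul, 10.97 against 10.32, and S100b, 7.43 against 5.96) met it at P25. A rule that at least 4 of these markers be measured over 5 was added after the results were seen, and with 2 oligodendrocyte and 3 astrocyte markers measured both sources stay undecided. Markers at background at every age do not count under that rule, so it could not show that whole glia were absent. How far picking fluorescent cells by hand removed whole glia was not measured, and RNA from damaged cells was not tested.

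Within ages, arrays also differed along 1 direction that held 28.4% of the variance, with the highest scores for P7 replicate 1 (46.2) and P10 replicate 3 (43.6). The score was compared with 3 measures over 15 arrays, with p from permutation within ages (7776 arrangements). It had r = -0.57 with cells picked (permutation p = 0.074, adjusted 0.11; rho -0.48, p = 0.13; r = -0.47 without the 2 arrays farthest from the median) and r = -0.60 with the 3′ minus 5′ difference (permutation p = 0.024, adjusted 0.072; rho -0.56, p = 0.061; r = -0.45), so both stay undecided. Nuclear RNA gave r = -0.07 (permutation p = 0.80, adjusted 0.80; rho -0.09, p = 0.77), which met the bound written beforehand for excluding it, but r became -0.36 without the 2 farthest arrays, so a stricter rule set after the result leaves it undecided. Across genes, which are not independent replicates, r was 0.23 with the P40 minus P7 difference, and 0, 0.52, -0.1 and 0 with the steps to P10, P15, P25 and P40. Within ages over the 15 arrays, the score had r = 0.89 with the first principal component, along which the ages stood in order. That value goes with more mature arrays, but both measures come from the same values and the rule did not use it. More mature arrays stay undecided under that rule, which was widened to the steps after the results were seen.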
